A study of Rattus norvegicus with 23 samples.

How the data were processed

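The samples were 3D aggregates of brain cells from Sprague Dawley rat embryos at embryonic day 15, grown for 14 days under agitation with medium replenished every 3 days, per the labels' protocols. Aggregates received 120 ng/ml sepiapterin or, as control, phosphate-buffered saline (PBS), and RNA was taken at 6, 12 and 24 hours (T6, T12 and T24). A control group at 0 hours (T0) was also included. Polyadenylated RNA was sequenced as stranded libraries made from 500 ng of total RNA. The labels' protocols state that libraries were made in 2 batches, with T6 and T12 in the first and T24 together with repeats of 2 T12 controls in the second. The batch of the T0 libraries is not given in the sources used here.

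The authors deposited raw read counts per gene, 1 table per library, with 32494 Ensembl gene identifiers and 5 summary lines. Reads were trimmed with cutadapt 1.8, aligned with STAR 2.5.2b and counted with HTSeq 0.6.1 against the rat build Rnor_6.0, per the submitters' processing notes. The strand setting of the counting and the annotation release are not given in the sources used here, so genes that overlap another gene on the opposite strand are uncertain, as are near-identical gene copies. The summary lines were left out of library sizes and tests. Relative to all alignments tallied, reads outside any gene made up 14.8 to 17.1%, reads aligned to several places 23.5 to 25.0%, and ambiguous reads 0.22 to 0.27%. Because reads with several alignments were not counted, members of multigene families are measured only through their unique parts.

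The files name genes by identifier only and do not pair identifiers with symbols. The reference table used here, of another assembly (GRCr8), had 47357 genes and no Ensembl identifiers, so 0 of the 32494 identifiers matched a symbol. The 32 gene lists fixed before the data were examined, which covered tetrahydrobiopterin synthesis, neurotransmitter enzymes, brain cell types and stress pathways, are made of symbols. None of the 32 was therefore tested, and genes are given by identifier with no statement of what they do.

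Groups were taken from the sample titles and treatment labels. There were 7 groups of 3 libraries (T0 control, and control and sepiapterin at T6, T12 and T24) and 2 repeated T12 control libraries. Samples numbered 10 and 11 each had a pair of libraries, and for these the titles and the column headers inside the files disagreed: the libraries titled 10 and 11 carried the headers of the repeats, and the reverse. The grouping by title had been chosen before the data were examined and gives the main values. Where T12 controls enter a comparison, the count of changed genes by file header is printed beside the main count. Other values, among them the alternatives and the fits without single libraries, are by title unless stated. For T6, T24 and T0 comparisons the grouping by file header was added after seeing the data. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

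Differences were tested with edgeR 4.0.16 (R 4.3.3), using quasi-likelihood fits with robust spread estimates, TMM scaling and the filterByExpr filter with its minimum count of 10. A single fit of 21 libraries in 7 groups, with 14 residual degrees of freedom, gave each sepiapterin contrast, their average over the 3 times, the differences between times of the sepiapterin effect, and the control contrasts of T6 against T0 and T12 against T6. It tested 14035 genes. T24 was compared with T12 in controls from the 3 T24 controls and the 2 libraries titled as repeats, which lie within the second batch only if the titles are right, with the T24 sepiapterin libraries adding to the estimate of spread. Repeat libraries were compared with the other libraries of samples 10 and 11 with sample number as a block. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene is called changed below 0.05. Log2 fold changes are given with standard errors (SE). Levels are TMM-scaled CPM, as mean ± SD. Sets of genes were tested with fry and camera (limma 3.58.1), camera with its preset correlation of 0.01 and with an estimated one.

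The rule for naming genes, fixed before the data were examined, took the genes with the smallest p-values and no overlap between groups in the sepiapterin contrasts, and the largest folds among genes with a mean log2 CPM of at least 1 in the contrasts between times and libraries. It also required a symbol. As no symbols were available from the sources used here, that requirement was dropped and at most 2 genes that rose and 2 that fell were taken per comparison, in the rule's order. Any other gene is stated to have been chosen after its values were seen.

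The depth was 16991417 to 26588314 reads in genes per library. The median standard error of a log2 fold change between a pair of groups was about 0.08, so a typical 95% interval extended 0.16 to either side. The test was run on simulated counts with the real library sizes and gene means, in a single run per time point. Genes of low average expression were not drawn as changed, and noise was independent between genes. Variation shared by many genes of a library was not simulated, so recovery may be overstated and false calls understated. In a simulation of the T6 contrast over 13966 genes, 50.7% of genes changed 1.25-fold, 77.6% of those changed 1.5-fold and 98.5% of those changed 2-fold were recovered, and 7 of 158 calls were false. In the T12 simulation over 13968 genes the shares were 55.2, 77.6 and 97.0%, with 10 of 163 calls false. In the T24 simulation over 13966 genes they were 56.7, 86.6 and 89.4%, with 6 of 161 calls false.

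Alternatives were DESeq2 size factors in the same fit, library size without composition factors, the DESeq2 1.42.0 Wald test, no filter, a filter of 1 CPM, an adjusted p of 0.10, limma voom with sample quality weights, 1 surrogate variable (sva 3.50.0), fits of a single time point, adding the counts of both libraries of samples 10 and 11, a batch term with all 5 T12 controls, and leaving out each library in turn. Replicate pairs were checked for identical libraries by the chi-square of their counts per degree of freedom, which ranged from 2.22 to 31.2, so each library was counted on its own. Regroupings of the samples were refitted with all splits where 6 libraries were compared, and with 100 drawn splits where the contrast spanned several times.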

Results

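Gene expression was measured by RNA sequencing in 3D aggregates of embryonic rat brain cells, a culture in which dissociated brain cells reassemble into spheres. The aggregates were exposed to sepiapterin or to the PBS vehicle. Sepiapterin is a pteridine that cells convert to tetrahydrobiopterin, the cofactor of the aromatic amino acid hydroxylases and of the nitric oxide synthases. Sapropterin, named in the title of the series, is a synthetic form of tetrahydrobiopterin given to patients with phenylketonuria, in whom phenylalanine accumulates. The design asks whether raising this cofactor changes gene expression in developing brain tissue after 6, 12 or 24 hours. Each of the 7 groups had 3 libraries, and 2 T12 controls had a repeat library.

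Reads assigned to genes numbered 20711380 to 22671840 per library in T0 controls, 21662777 to 26588314 in T6 controls and 22106299 to 23797639 with sepiapterin at T6. They numbered 19616350 to 21901345 in T12 controls, 20217962 and 20238280 in the T12 repeats, and 23783206 to 24637779 with sepiapterin at T12. T24 controls had 17693252 to 19018553 and the sepiapterin libraries at T24 had 16991417 to 19369187. Between 16608 and 17439 genes had reads in a library, and the 10 most abundant genes took 4.31 to 5.07% of the reads.

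The first component of the principal component analysis held 26.6% of the variance and the second 18.6%. Scores on the first ran from 5.62 to 9.36 at T6, -8.01 to 1.78 at T12 and -12.22 to -5.58 at T24. T6 and T12 share the first library batch by label, apart from the repeats, and did not overlap on the first component, whichever libraries are the repeats. By label T24 is in another batch, and the batch of T0 is not given. The positions of T24 and T0 on these axes therefore do not tell time from batch. T0 control replicate 1 stood apart from the other T0 controls, at root mean square distances of 0.250 and 0.282 log2 units, against 0.128 between those controls and at most 0.172 within any other group. The T12 controls titled 10 and 11 lay 0.166 and 0.163 from the T12 control titled 12, while the libraries titled as their repeats lay 0.130 and 0.127 from it.

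**Figure D1:**
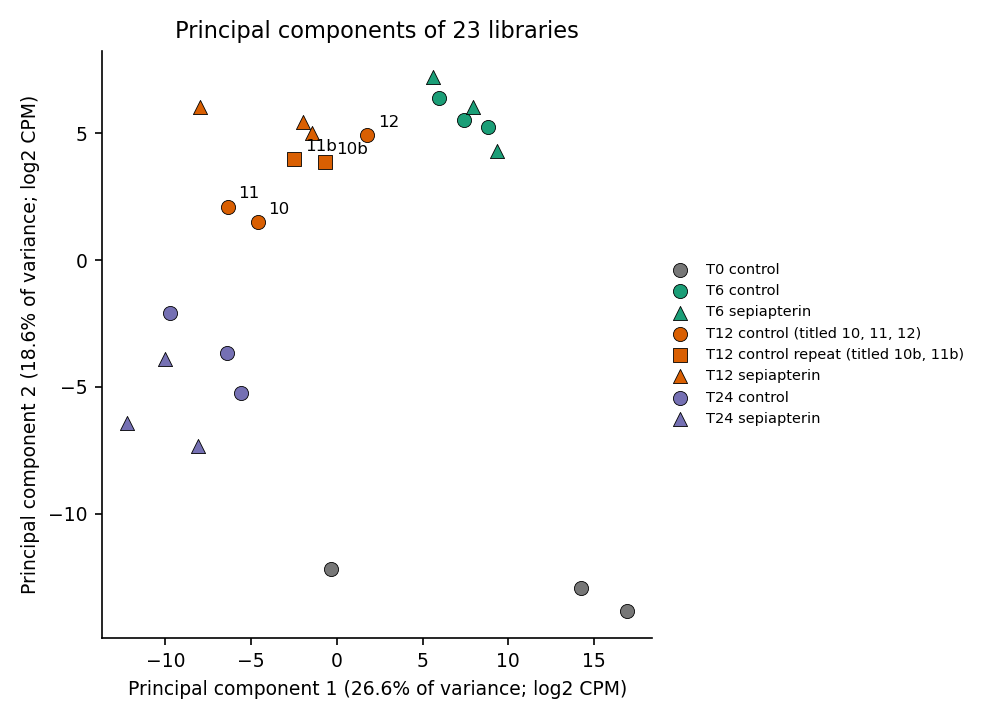
Scores of the 23 libraries on the first and second principal components of log2 CPM (percent of variance on each axis), with colour for time, circles for controls, triangles for sepiapterin and squares for the libraries titled as repeats of T12 controls. T0 control replicate 1 has a score of -0.34 on the first component against 14.22 and 16.92 for the other T0 controls.

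At 6 hours no gene passed the test between sepiapterin and control aggregates. Of 14035 genes tested with edgeR, 0 were changed and 301 had an unadjusted p under 0.05. DESeq2 and limma voom with quality weights also called 0. The 301 genes are under a share of 0.05, so the edgeR test may be conservative here. Its spread was estimated jointly with groups that vary more. The root mean square SD was 0.081 log2 units in T6 controls and 0.093 with sepiapterin at T6, but 0.162 in T0 controls. The count of 0 is thus not on equal terms with those at later times. ENSRNOG00000013009, which fell at later times, stood at 163 ± 2.60 CPM with sepiapterin and 181 ± 3.61 CPM in controls (n = 3 each), a log2 fold change of -0.15 ± 0.05 (SE) with an adjusted p of 1. ENSRNOG00000012404, another gene lower at later times, stood at 1.57 ± 0.10 and 2.72 ± 0.75 CPM, a log2 fold change of -0.77 ± 0.21 (SE) with an adjusted p of 1. Sepiapterin libraries all lay above or all below the controls for 10.7% of genes, where chance gives 10%. In the simulation of this contrast, 50.7% of genes changed 1.25-fold were recovered. Its noise was independent between genes, with the same spread of a gene in every group. A fit of the T6 libraries alone called 1 gene.

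At 12 hours 3 genes were changed, 1 higher and 2 lower with sepiapterin. ENSRNOG00000012404 fell 2.63-fold, from 2.44 ± 0.13 CPM in controls to 0.92 ± 0.10 CPM (SD, n = 3 each), with a log2 fold change of -1.39 ± 0.24 (SE) and an adjusted p of 0.029. ENSRNOG00000013009 fell 1.25-fold, from 211 ± 5.79 to 169 ± 13.9 CPM, with a log2 fold change of -0.32 ± 0.05 and an adjusted p of 0.029. ENSRNOG00000046428 rose 1.20-fold, from 74.9 ± 2.36 to 90.1 ± 2.37 CPM, with an adjusted p of 0.041. With T12 controls taken by file header, 10 genes were changed (7 higher, 3 lower), 2 of them shared with the grouping by title. The genes that fell kept their calls under that grouping, with log2 fold changes of -1.50 for ENSRNOG00000012404 (adjusted p 0.019) and -0.30 for ENSRNOG00000013009 (adjusted p 0.024). ENSRNOG00000046428 lost its call, at a log2 fold change of 0.16 and an adjusted p of 0.16. Over all alternatives the adjusted p-values ranged from 0.0012 to 0.33 for ENSRNOG00000012404, from 5e-05 to 0.33 for ENSRNOG00000013009 and from 0.0012 to 0.46 for ENSRNOG00000046428. Sepiapterin and control libraries did not overlap for 22.3% of genes, against 10% by chance, and 2231 genes had an unadjusted p under 0.05.

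The count at 12 hours rested on single libraries and on the method. It was 0 without T12 control replicate 1, control replicate 2, sepiapterin replicate 2 or sepiapterin replicate 3, and 1 without sepiapterin replicate 1. It was 309 without control replicate 3, the sample titled 12. That fit leaves control replicates 1 and 2, whose titles and file headers disagree. If the headers are right, second-batch controls are there compared with first-batch sepiapterin libraries. Batch and treatment cannot then be told apart in the 309 genes. DESeq2 called 227 genes, 3 of them shared with edgeR. Voom with quality weights, 1 surrogate variable, the looser threshold and the absence of a filter also raised the count.

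At 24 hours 585 of 14035 genes differed between sepiapterin and control aggregates, 291 higher and 294 lower with sepiapterin. ENSRNOG00000004100 rose 2.04-fold, from 3.29 ± 0.44 to 6.72 ± 0.26 CPM (SD, n = 3 each), with a log2 fold change of 1.03 ± 0.12 (SE) and an adjusted p of 0.00021. ENSRNOG00000042029 rose 1.42-fold, from 20.8 ± 0.74 to 29.6 ± 1.90 CPM, with an adjusted p of 0.00024. ENSRNOG00000013009 fell 1.31-fold, from 258 ± 7.44 to 197 ± 12.6 CPM, with an adjusted p of 0.00031. ENSRNOG00000042289 fell 1.21-fold, from 213 ± 3.92 to 176 ± 9.67 CPM, with an adjusted p of 0.0036. ENSRNOG00000012404, chosen here after its values were seen because it had fallen at T12, was again lower at 2.25 ± 0.38 against 3.71 ± 0.85 CPM, with an adjusted p of 0.044 and a range of 0.029 to 0.27 over the alternatives. The first 4 of these genes kept their calls in all 17 alternatives run.

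Changes at 24 hours were small. The median absolute log2 fold change of the 585 genes was 0.27, 48 changed by 1.5-fold or more and 9 by 2-fold or more. Sepiapterin libraries lay wholly above or below the controls for 549 of the 585 genes, and for 23.5% of all genes against 10% by chance. With T12 controls taken by file header, which enters this contrast only through the shared scaling, filter and estimate of spread, 818 genes were changed (344 higher, 474 lower), 574 of them shared.

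The number of genes called at 24 hours depended on each of the 6 libraries. It was 11 without sepiapterin replicate 1, 53 without sepiapterin replicate 2 and 1463 without sepiapterin replicate 3. That library lay 0.152 to 0.158 log2 units from the 3 T24 controls, and 0.167 and 0.172 from the other T24 sepiapterin libraries. Genes that differ between the paired libraries of samples 10 and 11 were looked up at T24 after their values were seen. ENSRNOG00000013579 and ENSRNOG00000053452 stood at 27.9, 27.3 and 14.6 CPM in sepiapterin replicates 1, 2 and 3 against 12.2 to 13.9 CPM in controls, and at 4.30, 3.90 and 6.18 against 6.51 to 9.24 CPM. ENSRNOG00000021177 stood at 43.6, 43.4 and 40.3 against 34.9 to 38.9 CPM. Replicate 3 was nearest to the controls in these, but not in ENSRNOG00000055241, at 2.75, 2.34 and 2.44 against 1.61 to 2.23 CPM. The count was 226, 87 and 117 without control replicates 1, 2 and 3. The log2 fold changes of the 585 genes moved less than the counts, to a median of 0.86 to 1.18 times their full value over the 6 fits. These fits share their remaining libraries with the full fit. A fit of the T24 libraries alone called 196 genes, 157 of them shared.

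**Figure D2:**
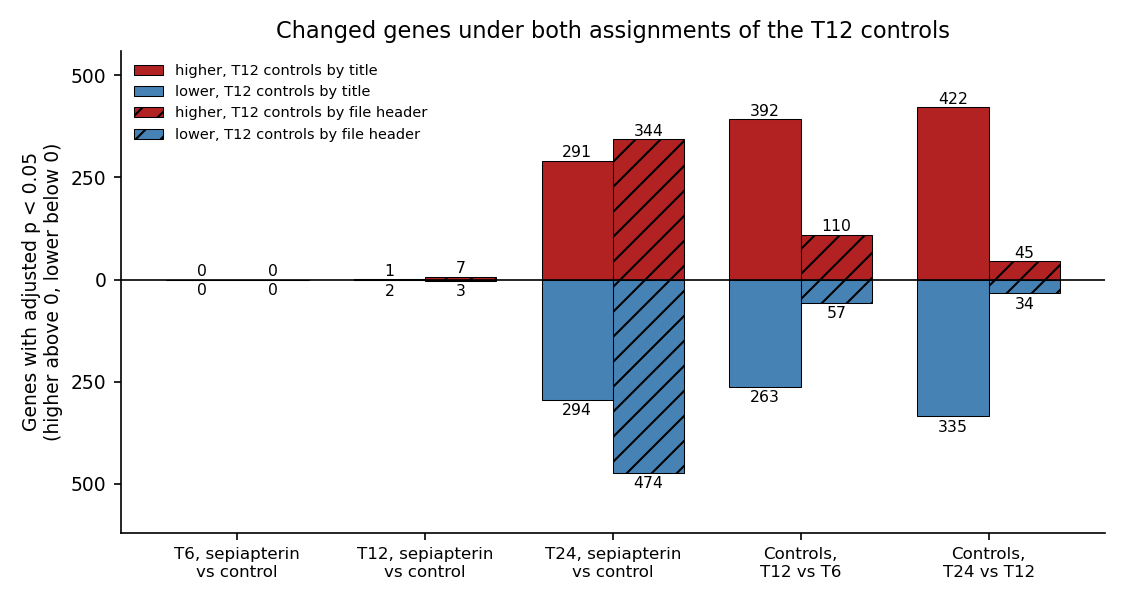
Number of genes with an edgeR adjusted p below 0.05 in 5 comparisons (horizontal axis), higher above 0 and lower below 0, with plain bars for T12 controls by sample title and hatched bars for T12 controls by file header. Between sepiapterin and control libraries 0, 3 and 585 genes differed at T6, T12 and T24 by title. The control comparisons that use T12 fall from 655 to 167 and from 757 to 79 genes between the groupings. With library size as the only scaling, lower genes outnumber higher ones in both control comparisons by title.

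The genes changed at 24 hours were examined as sets in the earlier contrasts, which share no library with them. At T6, 53.3% of the 291 genes that rose and 53.7% of the 294 that fell had the same direction, with limma fry p-values of 0.83 and 0.97. At T12 by title, 61.9% and 78.2% had the same direction (fry p 0.28 and 0.067). Camera with its preset correlation gave p = 0.0019 and p = 1.8e-09 for these sets at T12, and p = 0.43 and p = 0.18 with an estimated correlation. By file header the shares at T12 were 53.3% and 58.5% (fry p 0.69 and 0.40), and camera gave p = 0.16 and p = 0.011 with the preset correlation and p = 0.72 and p = 0.57 with an estimated one. All 8 fry tests had Benjamini-Hochberg adjusted p-values of 0.54 or more.

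Averaged over the 3 times, 144 genes differed between sepiapterin and control aggregates, 85 higher and 59 lower, with a median absolute log2 fold change of 0.18. The T24 libraries are part of this average: 59 of the 85 higher genes and 41 of the 59 lower genes were also called at T24. Its log2 fold changes correlated at 0.73 with those at T24, while those of single times correlated at 0.03 to 0.14 with each other. ENSRNOG00000013009 fell by 0.29 ± 0.03 on the log2 scale (SE, adjusted p 1.4e-05), and ENSRNOG00000012404 fell by 0.96 ± 0.12 (adjusted p 0.00027). ENSRNOG00000005600 rose by 0.28 ± 0.04 on the log2 scale (adjusted p 0.00024), with 0.09, 0.27 and 0.47 at T6, T12 and T24. ENSRNOG00000005387 rose by 0.21 ± 0.03 (adjusted p 0.00037), with 0.09, 0.18 and 0.37. Each of the 4 genes kept its call in all 31 alternatives run. By file header 101 genes were changed (55 higher, 46 lower), 68 of them shared with the grouping by title. By label T6 and T12 form the first batch and T24 the second, and the counts within each are those given for these times. Leaving out 14 of the 18 libraries in turn moved the count by over 1.5 times, down to 33 without T6 sepiapterin replicate 3 and up to 446 without T24 sepiapterin replicate 3. The other 4 were T6 sepiapterin replicate 1, T12 sepiapterin replicates 1 and 2 and T24 control replicate 1. DESeq2 called 450 genes.

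**Figure D3:**
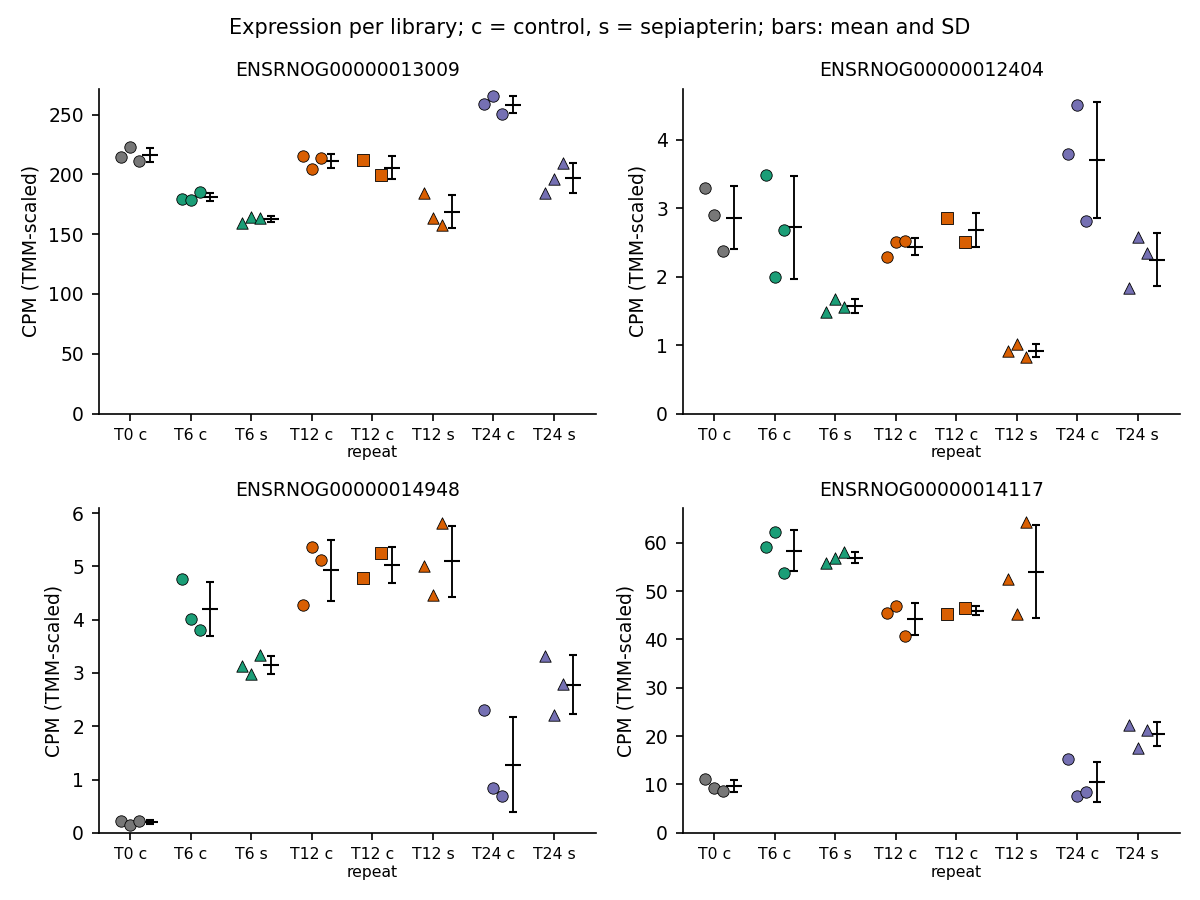
Levels of 4 genes in each library (TMM-scaled CPM, vertical axis) by group, with c for control, s for sepiapterin, and bars for the mean and SD. ENSRNOG00000013009 and ENSRNOG00000012404 are lower with sepiapterin at T12 and T24, while ENSRNOG00000014948 and ENSRNOG00000014117 rise in controls from T0 to T6 and are lower in T24 controls than in T12 controls.

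The effect of sepiapterin was compared between times by testing the difference itself. Between T24 and T12 it differed for 33 genes, 30 with the higher value at T24 and 3 with the lower. For ENSRNOG00000031706 the log2 fold change was -0.39 ± 0.13 at T12 and 0.82 ± 0.12 at T24, a difference of 1.21 ± 0.18 (SE, adjusted p 0.0072). For ENSRNOG00000030871 it was -0.20 at T12 and 0.26 at T24, a difference of 0.46 ± 0.08 (adjusted p 0.018). ENSRNOG00000060211 went the other way, from 0.21 to -0.30, a difference of -0.51 ± 0.09 (adjusted p 0.021). ENSRNOG00000055319 went from 0.12 to -0.21, a difference of -0.34 ± 0.06 (adjusted p 0.028). None of these 4 genes passed the test at T12 alone, with adjusted p-values of 0.15, 0.095, 0.14 and 0.20. By file header 143 genes differed (75 higher, 68 lower), 21 of them shared. Leaving out single libraries gave counts from 0 without T12 control replicate 1 to 567 without T24 sepiapterin replicate 3, and 11 of the 12 libraries moved the count by over 1.5 times, the exception being T12 sepiapterin replicate 2.

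No gene had a different effect at T24 than at T6 with edgeR, where 1662 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.063. DESeq2 called 53 genes, limma voom with quality weights 515, and edgeR by file header 5. Without T24 sepiapterin replicate 3 the count was 372, without T24 control replicate 1 it was 3 and without T24 control replicate 2 it was 1. Between T12 and T6, 0 genes differed, with 1049 at an unadjusted p under 0.05, and by file header 0 and 879. DESeq2 called 0 genes there, limma voom with quality weights 56, and edgeR 2 without T12 control replicate 3. By edgeR with the grouping by title, no single gene thus passed the test for a different effect at T24 than at T6, despite calls at T24 and none at T6.

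In controls, 3035 of 14035 genes differed between T6 and T0, 1532 higher and 1503 lower at T6. ENSRNOG00000014948 rose 20.4-fold, from 0.20 ± 0.04 to 4.20 ± 0.50 CPM (SD, n = 3 each, adjusted p 8.3e-09). ENSRNOG00000014117 rose 6.04-fold, from 9.69 ± 1.27 to 58.3 ± 4.25 CPM (adjusted p 1.9e-07). ENSRNOG00000008015 fell 3.43-fold, from 14.8 ± 4.30 to 4.27 ± 0.59 CPM (adjusted p 9.8e-07). ENSRNOG00000019422 fell 3.24-fold, from 34.7 ± 3.22 to 10.6 ± 1.22 CPM (adjusted p 4.6e-11). Among the 3035 genes, 74 changed by 2-fold or more. With library size as the only scaling the split was 2020 higher and 1047 lower. The count was 3200 without T0 control replicate 1, the library that stood apart, with 2361 genes shared. The labels do not place the T0 libraries in a batch. Libraries were scored on the gene differences between the paired libraries of samples 10 and 11. On this score T0 controls lay at 0.13 to 0.14, T6 controls at 0.09 to 0.23 and T24 libraries at -0.39 to -0.16. If the pairs differ by preparation, this argues against T0 sharing the batch of T24. A separate preparation of the T0 libraries is not excluded, so a part of batch in this comparison stays open.

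Between T12 and T6 controls 655 genes differed, 392 higher and 263 lower at T12. ENSRNOG00000017645 rose 2.76-fold, from 1.03 ± 0.05 to 2.87 ± 0.21 CPM (SD, n = 3 each, adjusted p 0.034), and ENSRNOG00000003537 rose 1.95-fold, from 5.53 ± 0.56 to 10.9 ± 1.45 CPM (adjusted p 0.0088). ENSRNOG00000050046 fell 1.90-fold (adjusted p 0.031) and ENSRNOG00000058068 fell 1.84-fold (adjusted p 0.044). By file header 167 genes differed, 110 higher and 57 lower, 140 of them shared. Under that grouping both genes that rose kept their calls, with log2 fold changes of 1.62 for ENSRNOG00000017645 (adjusted p 0.047, range over the alternatives 0.0031 to 0.14) and 0.94 for ENSRNOG00000003537 (adjusted p 0.019, range 8.6e-05 to 0.053). Both genes that fell lost their calls, with adjusted p-values of 0.18 and 0.099 (ranges over the alternatives 0.0054 to 0.18 and 0.0047 to 0.23). With library size as the only scaling the split by title was 256 higher and 415 lower. The count was 77, 105 and 1398 without T12 control replicates 1, 2 and 3, and 193, 236 and 104 without T6 control replicates 1, 2 and 3. The fit with 1398 genes keeps only the T12 controls whose titles and file headers disagree. If the headers are right, it crosses the library batches and cannot tell time from batch.

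Between T24 controls and the T12 controls titled as repeats 757 of 13653 genes differed, 422 higher and 335 lower at T24. ENSRNOG00000014117 fell 4.37-fold, from 45.9 ± 0.94 (n = 2) to 10.5 ± 4.19 CPM (n = 3), with an adjusted p of 0.0066, and ENSRNOG00000014948 fell 3.87-fold, from 5.02 ± 0.34 to 1.27 ± 0.89 CPM, with an adjusted p of 0.006. ENSRNOG00000053452 rose 3.55-fold (adjusted p 0.00029) and ENSRNOG00000032902 rose 2.61-fold (adjusted p 0.0024). By file header 79 genes differed, 45 higher and 34 lower, 67 of them shared. If the headers are right, the count by title crosses the library batches and the count by header lies within the second. Under that grouping the genes that fell kept their calls, each with an adjusted p of 0.024 (highest over the alternatives 0.099 and 0.083). ENSRNOG00000053452 had a log2 fold change of 0.15 (adjusted p 0.80, range 4e-14 to 0.82) and ENSRNOG00000032902 of -0.23 (adjusted p 0.63, range 2.6e-06 to 0.87). With library size as the only scaling the split by title was 273 higher and 519 lower. The count was 22 and 45 without T12 control repeats 1 and 2, and 1208, 211 and 214 without T24 control replicates 1, 2 and 3. These T24 controls also enter the sepiapterin contrast at 24 hours, in which ENSRNOG00000014948 and ENSRNOG00000014117, looked up after their values were seen, were higher with sepiapterin by 1.11 ± 0.28 and 0.96 ± 0.20 on the log2 scale (SE, adjusted p 0.028 and 0.020). Each of the pair lost that call in 5 of 17 alternatives.

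The libraries of samples 10 and 11 form pairs that compare library preparations, provided that each pair came from the same culture, which is not settled here. With sample number as a block, 2527 of 13505 genes differed between the libraries titled as repeats and the others, 1197 higher and 1330 lower in the repeats, with a median absolute log2 fold change of 0.16. This fit has almost no residual degrees of freedom, so its spread was largely borrowed across genes and the count is uncertain. By file header the same genes differ and each direction turns over, as the libraries titled repeats are then the first preparation. By title, ENSRNOG00000021177 was 2.30-fold higher in the repeats, at 84.3 and 76.8 CPM against 37.1 and 33.1 CPM, and stood at 70.4 CPM in the T12 control titled 12 and 34.9 to 43.6 CPM in the T24 libraries. ENSRNOG00000013579 was 2.18-fold higher, at 29.8 and 24.4 CPM against 12.3 and 12.6 CPM, and stood at 27.0 CPM in control 12. ENSRNOG00000055241 was 3.88-fold lower in the repeats and ENSRNOG00000053452 3.21-fold lower, the latter at 2.46 and 2.11 CPM against 7.35 and 7.41 CPM, with 1.97 CPM in control 12. Without the block 988 genes differed, and DESeq2 called 277.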

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

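The tests of surrogate variation, of composition scaling and of library preparation, the splits that keep the T24 arms, and the grouping by file header for the T24 and T24-against-T6 counts, were chosen after the results they bear on had been seen; the test on thinned counts and the other regroupings were planned before their outcome was known.

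The effect of sepiapterin differed between T24 and T12 for 33 genes by a test of the difference itself, which is what singled this result out for a closer look. By file header the number was 143, with 21 genes shared. Of 100 splits of the libraries within T12 and T24, drawn with the real one included, 2 gave at least 33 genes. Most of these splits also break up the T24 arms and with them any effect at T24, so they say little about a difference between the times. The highest other split gave 125 genes. It left the T24 arms as they were and joined the T12 controls titled 10 and 11 with T12 sepiapterin replicate 3, so it follows the pair of libraries whose titles and file headers disagree. Exchanging most of the T12 arms adds only a part of the T12 effect to the T24 effect. With the T24 arms kept, joining controls 10 and 11 with a T12 sepiapterin library gave 67, 29 and 125 genes. Other exchanges of 2 controls gave 37, 0, 1, 9, 4 and 2 genes. The count was thus mostly higher where the libraries titled 10 and 11 moved together, and structure beyond treatment stays open. If the headers are right the count by file header is the within-batch value. With the T24 arms kept, 5 of the 20 assignments of the T12 libraries gave at least 33 genes, the highest 828 with the T12 arms exchanged, and 20 are too few for a share under 0.05. The differences of T12 against T6 and of T24 against T6 had 0 genes in the real split, a count that each of the 100 drawn splits reaches by definition, so the splits (highest 24 and 12) say nothing about these.

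The T24 side rests on 585 genes. The real split of the 6 libraries gave 585 and the highest of the other 9 splits gave 0, but only 10 splits exist, too few for a share under 0.05. Averaged over times, 1 of 100 splits, the real one, reached 144 genes and the highest other gave 0. Most of these splits also break up the T24 arms, whose calls make up most of the 144 genes. They therefore cannot tell an effect shared by the times from the T24 contrast. As replicates may be technical, the splits also do not exclude a chance difference between cultures. A difference in sampling depth between the T24 arms is argued against by their reads, 18293007 per library in controls and 18035630 with sepiapterin on average, with overlapping ranges. Thinning all libraries to the smallest total, 16991417 reads, therefore changes these libraries little and is a weak test, in which 508 of the 585 genes stayed past the threshold. Without composition factors 548 of the 585 stayed, so the scaling does not account for most calls. With 1 surrogate variable in the model 513 stayed. That variable was estimated from the variation left over by the groups. It could therefore remove little of what differs between the T24 arms and is a weak test. Library preparation was tested through the gene differences between the paired libraries of samples 10 and 11, which share no library with T24. The calls between these pairs come from a fit with almost no residual degrees of freedom. Of 584 genes called at T24 and tested there, 184 were also called between the paired libraries against 109.3 by chance, 146 of them in the same direction. Across 13496 genes the correlation with the T24 difference was 0.074, within the range of -0.153 to 0.153 over the other labellings of the T24 libraries (exact permutation p 0.40, two-sided). With each library's score on these differences in the model 531 of the 585 genes stayed. The T24 arms overlap on this score, at -0.39 to -0.21 in controls and -0.38 to -0.16 with sepiapterin. The adjustment could therefore remove little and is a weak test. As the 184 shared calls exceed the 109.3 expected by chance, a part of preparation in the T24 calls stays open, as do preparation effects on other genes. An effect of sepiapterin at 24 hours remains a hypothesis consistent with these tests, and a difference between the arms in culture or handling, for which the labels give no variable, stays open and untested.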

How the results depend on the processing

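The grouping by file header for contrasts without T12 controls and for T24 against T12 controls, the batch term by file header and the block by sample number offset were chosen after seeing the data; other alternatives were fixed before. Where no value is given for a setting that was run, the count stayed within 1.5 times the main one. Voom was not run for T24 against T12 controls and repeat libraries, nor the surrogate variable for these and T6 against T0. Counts of sepiapterin genes at T6, T12 and T24 were 0, 3 and 585, and 144 on average; the effect differed for 0 genes (T12 against T6), 0 (T24 against T6) and 33 (T24 against T12).

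DESeq2 size factors, library size as the only scaling and the 1 CPM filter moved no count by over 1.5 times. The DESeq2 test gave 227 genes at T12, 450 on average, 53 and 161 for the effect at T24 against T6 and T12, and 277 between repeat libraries. Without a filter the counts were 66 at T12, 227 on average, 18 and 63 for the effect at T24 against T6 and T12, and 1256 for T24 against T12 controls. At an adjusted p of 0.10 they were 214 at T12, 1246 at T24, 567 on average, 4 and 152 for the effect at T24 against T6 and T12, 1375 for T12 against T6 controls and 1555 for T24 against T12 controls. Voom with quality weights gave 958 at T12, 1745 at T24, 1371 on average, 56 for the effect at T12 against T6, 515 and 774 at T24 against T6 and T12, 4714 for T6 against T0 controls and 2797 for T12 against T6 controls. With 1 surrogate variable they were 150 at T12, 309 on average, 129 for the effect at T24 against T12 and 1018 for T12 against T6 controls. Fits of a single time gave 1, 16 and 196 genes at T6, T12 and T24, with fewer samples to estimate the spread. Other causes were not tested.

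By file header the counts were 10 at T12, 5 and 143 for the effect at T24 against T6 and T12, 167 for T12 against T6 controls and 79 for T24 against T12 controls. With all 5 T12 controls and a batch term they were, by header, 7 at T12, 167 for the effect at T24 against T12, 224 for T12 against T6 controls and 63 for T24 against T12 controls, and, by title, 235 on average and 56 for the effect at T24 against T12. Adding both libraries of a sample gave 342 for T12 against T6 controls, and T12 controls titled as the first batch gave 122 for T24 against T12. ENSRNOG00000032902, higher at T24 than at T12 in controls by title, reversed to -0.23 both by header and with the batch term by header; the cause was not tested.

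Leaving out single libraries gave 0 to 0 genes at T6, 0 to 309 at T12, 11 to 1463 at T24 and 33 to 446 on average. The 309 came without T12 control replicate 3, as did the highest count for T12 against T6 controls. If the file headers are right, both of these fits cross the library batches. The effect ranged from 0 to 2 (T12 against T6), 0 to 372 (T24 against T6) and 0 to 567 (T24 against T12). Control counts ranged from 2030 to 3200 (T6 against T0), 77 to 1398 (T12 against T6) and 22 to 1208 (T24 against T12). In the last of these, leaving out a repeat leaves 1 T12 library, assumed to vary like the other groups. Named genes with a call kept their direction in all these fits and lost their call in 70 of 248 of them. Genes named by the rule in comparisons of a pair of groups had no overlap between the groups. Their kept direction was therefore fixed by the choice and says nothing about stability. Under the other settings 25 of 361 calls were lost and 2 reversed.

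The repeat comparison had sample number as a replicate block, and without the replicate block it gave 988 genes. Elsewhere the labels state no pairing, though sepiapterin and control sample numbers differ by 95 throughout. Deviations from group means correlated at -0.108 to 0.143 over the 9 pairs this makes, over 0.1 in only 1, and in 3 of 9 the own number gave the control its highest value, so the samples were not treated as paired. With this offset as a replicate block the counts were 0 at T12, 358 at T24, 25 on average and 1 for the effect at T24 against T12. The gene lists were not run, since identifiers could not be matched to symbols. Depth and 3 libraries per group limit the detection of small changes. In the simulated contrasts, with noise independent between genes, about 50.7 to 56.7% of genes changed 1.25-fold were recovered.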

Other observations

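The distance test of exchanged titles, the test of a foreign library among the T0 controls, and the test of the T0-to-T6 genes at T24 were chosen after the patterns had been seen; the tests of sample identity across preparations and of depth were planned before their outcome was known, but the spread by which sample identity is judged was added afterwards.

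A pair of genes was lower with sepiapterin at several times. ENSRNOG00000013009 had log2 fold changes of -0.15, -0.32 and -0.39 at T6, T12 and T24, and ENSRNOG00000012404 of -0.77, -1.39 and -0.72. Both passed the test at T12 and T24 under either grouping of the T12 controls. Their T12 calls were lost in 5 of 20 and 6 of 20 alternatives, with adjusted p-values up to 0.33 for each. At T24 ENSRNOG00000013009 kept its call in all 17, and ENSRNOG00000012404 lost it in 6 of 16, with adjusted p-values up to 0.27. At T6 neither passed it, with adjusted p-values from 0.17 to 1 and from 0.33 to 1 over the alternatives.

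The libraries titled 10 and 11 lay apart from the T12 control titled 12. An exchange of titles with the repeats is a candidate explanation: both lay farther from control 12 than the libraries titled 10b and 11b did, by 0.036 log2 units on average, and nearer to the T24 libraries, at 0.192 and 0.174 against 0.207 and 0.193. They were also farther from the T12 sepiapterin libraries, at 0.193 and 0.166 against 0.173 and 0.147. Different cultures under the same sample number stay open: libraries sharing a number lay nearer across preparations than libraries of different numbers by -0.012 on average, with -0.003 and -0.020 for the 2 samples, a mean no larger than its spread. Each library was also scored on the gene differences between the pairs, with low scores toward the libraries titled 10 and 11. T24 libraries scored -0.39 to -0.16, while control 12 scored 0.24 and the T0, T6 and T12 sepiapterin libraries 0.09 to 0.29. These scores argue against the titles, which place the T24 libraries in the batch of 10b and 11b. The file headers point the same way as the distances. The libraries titled 10 and 11 are thus the likelier second-batch repeats, and the values by file header would then be the within-batch ones. No biological explanation was tested, as the design gives none for libraries of the same sample.

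T0 control replicate 1 lay 0.250 and 0.282 from the other T0 controls, which lay 0.128 apart. A library of another group of this series is argued against: its nearest library outside T0 was 0.233 away, above the largest distance of 0.172 within any other group. Depth is argued against: its 22168462 reads lie between the 20711380 and 22671840 of the other T0 controls. The excess distance was 0.138 with all reads and 0.134 after thinning all libraries to the same total. A sample from elsewhere, a different culture or uneven RNA quality were not tested and stay open.

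For T6 against T0 controls, where the labels do not give the batch of T0, the real split gave 3035 genes. The highest of the other 9 splits gave 0, with 1 of 10 splits reaching the real count. Between T12 and T6 controls the real split gave 655 genes and the highest other 3, again 1 of 10. For sepiapterin at T12 the values were 3 and 0, with 1 of 10 reaching the real count. These 10 splits are too few for a share under 0.05. At T6 the real split and the highest other both gave 0 genes, a count that 10 of 10 splits reach by definition, so that comparison says nothing.

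A hypothesis was tested that sepiapterin at 24 hours moves genes the way the first 6 hours of the time course do, as ENSRNOG00000014948 and ENSRNOG00000014117 rose strongly from T0 to T6 in controls and were higher with sepiapterin at T24. The T0 and T6 controls share no library with T24. The median log2 fold change at T24 was -0.02 for the 1532 genes that rose and 0.01 for the 1503 that fell, a difference of -0.032, opposite to the hypothesis and within the range of -0.041 to 0.041 over the other labellings (exact permutation p 0.20, two-sided, where the smallest possible is 0.10). Of the genes that rose from T0 to T6, 31 were higher and 41 lower with sepiapterin at T24, against 31.8 and 32.1 expected by chance. Of those that fell, 57 were higher and 40 lower, against 31.2 and 31.5. The 2 named genes are among the 31. Neither passed the test at T12, with adjusted p-values of 0.92 and 0.38.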
